A study of Mus musculus with 6 samples.

How the data were processed

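RNA from 6 samples of mouse microglia was sequenced, 3 given medium from ferroptotic bone marrow-derived macrophages and 3 given medium from normal ones. Per the labels' protocols, total RNA was extracted, libraries were made with an mRNA kit and amplified by PCR, and sequencing was on an Illumina NovaSeq 6000. Per the submitters' processing notes, fastp 0.17.1, HISAT2 2.1.0, DESeq2 1.18.1 and R 3.4.3 were used by the submitters. The genome build, the annotation, the counting tool and whether counting used strand are not given in the sources used here, so no coordinates are printed.

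The authors deposited a table of 26096 genes with a log2 value per library, group means, a log2 fold change, a p-value and a false discovery rate, and a shorter table of their changed genes that adds FPKM per library. The deposited log2 values behave as log2 of a count divided by a per-library size factor, plus 1: after undoing the log, 100% of values in each library were whole multiples, within 0.01, of what 1 read is worth. Size factors read from these steps were 1.02, 1.19 and 1.02 in the control libraries and 0.940, 0.977 and 0.903 in the others. The whole reads worked out in this way gave the depth per library, between 39624311 and 50557794, and whether they count reads or fragments is not given in the sources used here. Among low values a count of 3 was more frequent than 2 (6101 against 5169 values) and 5 more than 4 (3537 against 3005), so they may be estimated counts rounded to whole numbers, and read numbers and depths given here carry that doubt. The authors' log2 fold change equals the difference of the group means of these values, so it is on the log2(normalized count + 1) scale and understates the change of low genes. The authors' deposited p-values were used only to count their calls. The deposited FPKM values cover the 1699 genes of the shorter table, and their group means had the direction of the log2 values in 1363 of the 1363 that were tested here.

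The main test was limma 3.58.1 (trend and robust, two-sided) in R 4.3.3 on the deposited log2 values, with medium as the one term, for 15597 genes with at least 10 normalized counts in at least 3 libraries. Adjusted p-values are Benjamini-Hochberg values over these genes, and the threshold was 0.05. The plan made before the data were examined assumed raw counts or FPKM-like values and edgeR for raw counts, which was not run, as raw counts are not the deposited unit, and of the whole reads worked out only limma-voom made use; limma was what the plan named for FPKM-like values. For such values the plan set a minimum of 1 in at least 3 libraries, and the minimum of 10 normalized counts used here replaced it after the data were seen. With the minimum of 1, 20707 genes were tested and 6658 passed, and the list of trophic factors did not pass. SE is limma's moderated standard error, and means and SDs are of normalized counts over 3 libraries. At these depths, a gene at 10 normalized counts rests on about 10 reads per library, and means and SDs carry the spread between samples. The test was tested in a single run on simulated data for the 15597 genes of this comparison, with 200 genes changed. Every gene was drawn with the same dispersion (0.00264, the median). The test recovered 74% of genes raised 1.5-fold, 96% of those raised 2-fold, 100% of those raised 4-fold and 84% of those at 0.5 of their level, and 3.28% of all calls were false. In the real data 68 abundant genes spanned over 1.5 log2 units within a group, and 6629 genes passed. These rates describe the simulation and may not hold for the real data.

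Before the data were examined, 35 gene lists were fixed, and the 33 with at least 5 measured members were tested with camera (preset correlation 0.01, Benjamini-Hochberg over the lists), with an estimated correlation and with fry. Genes named in the text were the 10 largest rises and 10 largest falls among called genes with at least 10 CPM in the higher group, separated groups and a regular symbol; up to 4 members of each list with the smallest p-values; a fixed set of 14 genes; and, with 1 exception among p53 targets, members of a list wherever 5 or fewer are counted. Oas2 and Oasl1 were named under that last part. Members of gene families picked after the data were seen, Csf2, and genes that changed in a list only with quantile normalization were named after their values were seen. So were some genes below the low-count filter. Where a symbol stands on more than 1 gene ID (34 symbols), the ID with the highest mean stands for it. Itgam is such a symbol and is not reported by name. Of the gene IDs, 26051 (99.8%) are in GENCODE M21, which was used with bedtools 2.31.1 only to ask which gene models overlap.

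Replicate pairs within a group differed by more than sampling noise, with a chi-square per degree of freedom of 16.3 to 22.8, so no library looks like a copy of another; this does not show that the samples are independent cultures. Alternatives were a replicate block, leaving out each library, a pseudocount of 0.1, no low-count filter, quantile normalization, limma without trend and robust, and an adjusted p of 0.01. The minimum of 1 normalized count was run beside these. Added after the data were seen were limma-voom on the whole reads, total-count scaling, and leaving out genes with a wide spread. Tables were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.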

Results

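The data are RNA sequencing profiles of mouse microglia, the resident macrophages of the brain, that had received medium conditioned by bone marrow-derived macrophages. In 3 samples the medium came from macrophages undergoing ferroptosis, an iron-dependent form of cell death driven by lipid peroxidation, and in 3 samples it came from normal macrophages. The inducer of ferroptosis, the length of exposure and the source of the microglia are not given in the sources used here. The reads assigned to genes, worked out from the deposited values and possibly estimated rather than counted, numbered 43419446, 50557794 and 43829217 in the 3 control libraries and 40328420, 41953603 and 39624311 in the 3 libraries given ferroptotic medium. The 10 most abundant genes took 7.39% to 7.59% of the reads in the control libraries and 8.95% to 9.29% in the others. Nothing in the labels says that the samples came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

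Libraries grouped by medium. Across 15597 genes, the correlation of log2 values between libraries had a lowest value of 0.980 within a group and lay at 0.962 to 0.967 between the groups, where genes are not independent replicates. The first principal component, which separated the media, held 51.3% of the variance, and the second held 14.2%.

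The comparison asks how medium from ferroptotic macrophages alters gene expression in microglia. With ferroptotic medium, lists of cytokine and integrated stress response genes rose, and lists of interferon-stimulated and cell cycle genes fell. With an estimated correlation the cytokine and interferon-stimulated lists held, while the integrated stress response and cell cycle lists each had a camera adjusted p = 0.0519. Among single genes, the prostaglandin synthase gene Ptgs2 and the haem oxygenase gene Hmox1 rose. The largest rise among the genes named by size was that of Csf3 (ENSMUSG00000038067), which encodes the granulocyte growth factor G-CSF. It went from 1009.9 ± 43.8 to 38306 ± 594 normalized counts (SD, n = 3 per group), a log2 fold change of 5.24 (SE 0.04; limma adjusted p = 1.97e-11). Hmox1 (ENSMUSG00000005413), the haem-degrading enzyme haem oxygenase 1, went from 12488 ± 154 to 181437 ± 3178 normalized counts, a log2 fold change of 3.86 (SE 0.02; limma adjusted p = 1e-11). The largest fall was that of Cxcl10 (ENSMUSG00000034855), an interferon-inducible chemokine, from 1337 ± 46.7 to 159 ± 12.4 normalized counts, a log2 fold change of -3.06 (SE 0.09; limma adjusted p = 6.3e-08).

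In all, 6629 of the 15597 genes tested passed a limma adjusted p of 0.05, 3077 of them higher and 3552 lower with ferroptotic medium. Of these, 616 rose and 577 fell at least 2-fold. The other genes among the 10 largest rises were the neutrophil chemokine Cxcl2 (log2 fold change 4.47, SE 0.03), the cytokine Lif (4.45, SE 0.07), the prostaglandin synthase Ptgs2 (from 9475 ± 242 to 173963 ± 8879 normalized counts), Il6 (3.94, SE 0.20), the interleukin-1 family cytokine Il1f9 (3.76, SE 0.16), the collagenase Mmp13 (3.72, SE 0.14), the glutathione-degrading enzyme Chac1 (3.63, SE 0.07) and Urah (3.63, SE 0.11). Their limma adjusted p-values lay at or below 8.74e-07. The other large falls were in the interferon-induced Ifit3b (-2.67, SE 0.09), Mx1 (-2.59, SE 0.13) and Ifit3 (-2.57, SE 0.06), in Serpinb8 (-2.41, SE 0.09), the helicase Pif1 (-2.36, SE 0.09), the oxysterol receptor Gpr183 (-2.14, SE 0.08), and the mitotic genes Plk1 (-2.11, SE 0.05) and Cenpf (-2.11, SE 0.06). Ifit3 and Ifit3b are near-identical copies whose reads cannot be fully told apart. Rbm12 also fell (-2.41, SE 0.55; limma adjusted p = 0.0245), but it shares exons on the same strand with Cpne1, and without control replicate 1, 2 or 3 or ferroptotic replicate 1 its adjusted p rose to between 0.061 and 0.0737.

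**Figure D1:**
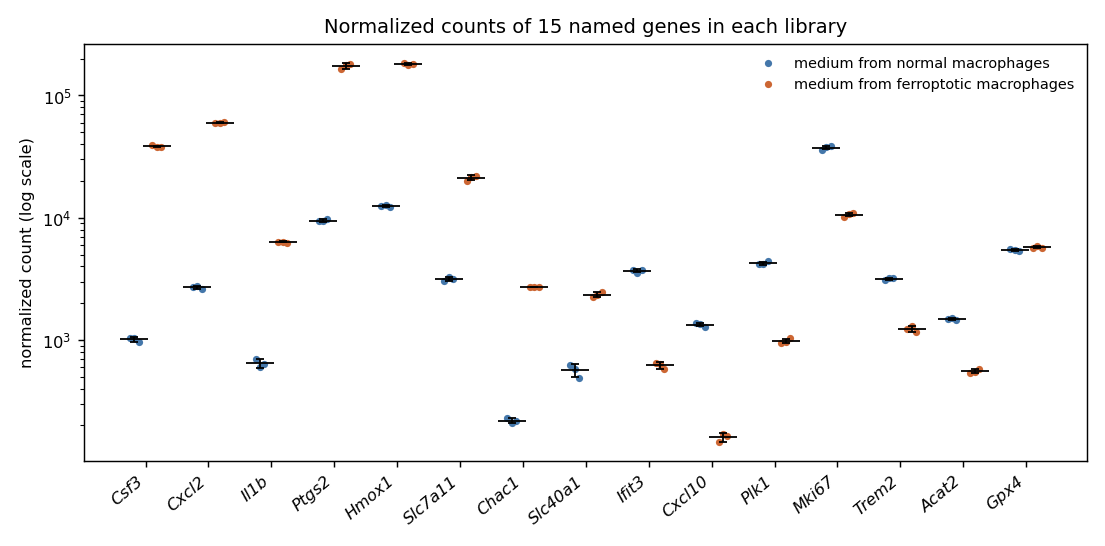
Normalized counts of 15 named genes (log axis) in each of the 6 libraries, blue for medium from normal macrophages and orange for medium from ferroptotic macrophages; each dot is 1 library and the black bars are the mean and the SD of 3 libraries. Csf3 lay near 1009.9 normalized counts in the control libraries and 38306 in the others, Cxcl10 went from 1337 to 159, and Gpx4 lay at 5456 and 5747, a difference that did not pass the test.

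Cytokine genes rose as a group. Of the 21 measured members of the list of proinflammatory cytokines and chemokines, 16 rose and 2 fell (17 and 2 when adjusted over the list alone), with a median log2 fold change of 1.61 (camera adjusted p = 3.03e-10; adjusted p = 0.0413 with an estimated correlation). Il1b, the secreted pyrogenic cytokine, went from a mean of 645 to 6342 ± 69.3 normalized counts (log2 fold change 3.30, SE 0.06), and Il6 from 57.7 ± 12.9 to 892 ± 153. Tnf rose less, from 19536 ± 218 to 35484 ± 360.4 (0.86, SE 0.02), as did the inducible nitric oxide synthase gene Nos2 (0.84, SE 0.04), and the chemokine Ccl3 rose by 1.61 (SE 0.02). The members that fell were Cxcl10 and Il18 (-0.92, SE 0.06). Of the 20 genes of NF-kB feedback and targets, 18 rose and 0 fell (20 and 0 when adjusted over the list alone), among them Nfkbiz (1.92), Nfkbia (0.97), Zc3h12a (0.89) and Tnip1 (0.61), with a median of 0.64 (camera adjusted p = 1.46e-10; adjusted p = 0.0519 with an estimated correlation). Of 25 immediate early genes, 19 rose and 0 fell, with a median of 0.66, led by Ier3 (1.31), Dusp5 (1.56), Zfp36 (1.26) and Atf3 (2.13; camera adjusted p = 3.27e-10). With an estimated correlation that list had an adjusted p = 0.0515. In the inflammasome and pyroptosis list, Casp1 (0.36), Casp4 (0.40), Nlrp3 (0.84) and Il1b rose while P2rx7 (-1.05), Il18 and Gsdmd (-0.34) fell, 4 and 3 of 12 measured members among 14 listed (camera adjusted p = 0.461). Pycard, with 11 reads over the 6 libraries, was below the filter. The list of alternative activation had 7 of 11 measured members higher and 0 lower (8 and 0 when adjusted over the list alone), with a median of 0.65 (camera adjusted p = 0.000385; adjusted p = 0.181 with an estimated correlation). It held 20 genes, so the result covers only the part that was measured. The members that rose included the angiogenic factor Vegfa (2.09), the interleukin-1 receptor antagonist Il1rn (1.46), Il4ra (1.62) and the chemokine Ccl22 (0.46). Mrc1, a mannose receptor, had 18.5 ± 7.75 and 17.9 ± 5.81 normalized counts (limma adjusted p = 0.965), and Arg1 had 37 reads over the 6 libraries, below the filter. Ccl17 (2 reads), Ccl24 (14) and Mgl2 (38) were below it too.

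Genes of the amino acid and redox stress responses rose. All 23 measured members of the integrated stress response, which follows phosphorylation of the initiation factor eIF2, rose, with a median log2 fold change of 1.55 (camera adjusted p = 4.24e-19; adjusted p = 0.0519 with an estimated correlation). Chac1 went from 219 ± 10.9 to 2718 ± 10.5 normalized counts, Cth, an enzyme of cysteine synthesis, rose by 2.67 on the log2 scale (SE 0.05), and the pseudokinase gene Trib3 rose by 2.65 (SE 0.06). Slc7a11, the cystine importer, went from 3161 ± 99.2 to 21209.7 ± 948 (2.75, SE 0.04). Of 23 members of the NRF2 oxidative stress response, 16 rose and 1, the epoxide hydrolase Ephx1 (-1.04), fell (17 and 1 when adjusted over the list alone). The median was 0.64 (camera adjusted p = 3.98e-08; adjusted p = 0.0547 with an estimated correlation), with the autophagy receptor Sqstm1 at 1.67 and the catalase gene Cat at 1.32. Of 25 ferroptosis regulators, 13 rose and 7 fell, with a median of 0.36 (camera adjusted p = 0.00198; adjusted p = 0.21 with an estimated correlation). The 4 named members of that list, Ptgs2, Hmox1, Chac1 and Slc7a11, also stand in other lists and rose. Gpx4, which reduces lipid peroxides, had 5456 ± 68.3 and 5747 ± 100.3 normalized counts (0.08, SE 0.03; limma adjusted p = 0.113). The 20 iron handling genes split into 9 that rose and 7 that fell and did not pass camera as a list (median 0.21, and 0.077 with quantile normalization; camera adjusted p = 0.112). The iron exporter Slc40a1 rose from 563 ± 69.6 to 2348 ± 105 (2.07, SE 0.09), the siderophore-binding Lcn2 from 536 ± 69.4 to 5247 ± 473 (3.29, SE 0.11), the haem transporter Slc48a1 by 1.34 and the metal transporter Slc11a1 by 0.76.

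Interferon-stimulated and proliferation genes fell. Of 28 interferon-stimulated genes, 26 fell and 0 rose, with a median log2 fold change of -0.89 (camera adjusted p = 2.13e-14; adjusted p = 0.0283 with an estimated correlation). Ifit3 went from 3681 ± 105 to 622 ± 39.5 normalized counts, and Ifit2 (-2.00), Cmpk2 (-1.86) and Rsad2 (-1.49) fell with it. Oas2 (-0.67, limma adjusted p = 0.134) and Oasl1 (-0.07, 0.862) did not pass. All 34 cell cycle genes fell, with a median of -1.50 (camera adjusted p = 4.86e-25; adjusted p = 0.0519 with an estimated correlation). Mki67, a marker of cycling cells, went from 37543 ± 1328 to 10618 ± 351 normalized counts (-1.82, SE 0.04), Ube2c fell by 1.93 and Rrm2 by 1.55 on the log2 scale, and Top2a went from 28521 ± 481 to 9951 ± 456. Among 24 p53 targets and apoptosis genes, 12 rose and 4 fell, with a median of 0.24 (camera adjusted p = 0.0249; adjusted p = 0.181 with an estimated correlation). Sesn2 (1.77), Plk2 (1.35) and Bcl2a1b (1.16), a member of a family of close copies, rose, and Gtse1 (-1.48), Sesn1 (-0.82) and Ei24 (-0.25) were among the 4 that fell.

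**Figure D2:**
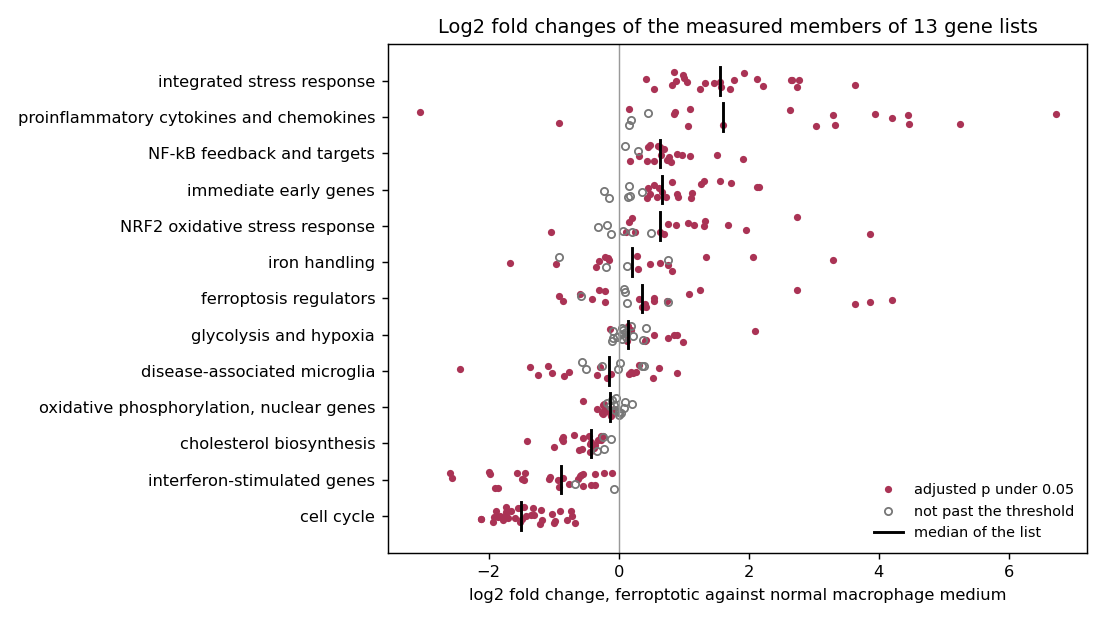
Log2 fold changes (ferroptotic against normal macrophage medium) of the measured members of 13 gene lists fixed before the data were examined; filled dots passed a limma adjusted p of 0.05, open dots did not, and black bars are the medians. All 34 cell cycle genes and 26 of 28 interferon-stimulated genes fell, and all 23 genes of the integrated stress response rose.

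Lipid genes moved in opposite directions. Of 24 genes of cholesterol biosynthesis, 20 fell and 0 rose, with a median log2 fold change of -0.43 (camera adjusted p = 5.26e-09; adjusted p = 0.0466 with an estimated correlation). Acat2 went from 1483 ± 23.1 to 556 ± 21.6 normalized counts (-1.42, SE 0.06), and Idi1 (from 1962 ± 124 to 982 ± 47.8) and Tmem97 (-0.88) also fell. Abca1, a cholesterol exporter, rose from 680.1 ± 57.0 to 2929.9 ± 50.9 (2.11, SE 0.07). Of 11 LXR targets and lipid efflux genes, Abca1, Lpcat3 (0.41) and Smpdl3a (0.34) rose, and Abcg1 (-0.65), Mylip (-0.58), Scd2 (-0.48), Srebf1 (-0.37) and Pltp (-0.31) fell (camera adjusted p = 0.504). Of 23 genes of fatty acid metabolism and lipid droplets, 10 rose and 7 fell (10 and 8 when adjusted over the list alone; camera adjusted p = 0.533). The droplet proteins Plin2 (0.90) and Hilpda (1.73) and the fatty acid carrier Fabp4 (1.05) rose, and Fasn, the fatty acid synthase, fell (-0.94).

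None of the lists of homeostatic, disease-associated, phagocytic, lysosomal, antigen presentation and complement genes passed camera, which compares a list with other genes. By fry, which asks only whether a list moves on balance, the homeostatic (fry adjusted p = 0.0012), disease-associated (2.77e-05), lysosomal (0.013) and complement lists (0.0219) were lower. Of 14 measured homeostatic genes, Rhob (1.14) and Bin1 (0.32) rose and 7 fell, among them the lipid receptor Trem2, from 3166 ± 69.5 to 1232 ± 67.6 normalized counts (-1.36, SE 0.06), Csf1r (-0.38) and Cst3 (-0.29; camera adjusted p = 0.306). Cx3cr1 had 335 ± 129 and 222 ± 63.1 normalized counts (-0.57, SE 0.34; limma adjusted p = 0.233). P2ry12 had 3 reads and Tmem119 had 21 reads over the 6 libraries, so a difference in either could not be tested. Depth was not the limit, as each library held 39624311 reads or more. Fcrls (5 reads), Gpr34 (5), C1qa (5), C1qb (14) and Mertk (34) were also scarce. The homeostatic counts rest on 14 of 23 listed genes, and the complement counts on 10 of 17. Of 26 disease-associated genes, 8 rose and 11 fell (camera adjusted p = 0.533): Lpl went from 22596 ± 233 to 9511 ± 409 (-1.25, SE 0.04), Gpnmb fell by 1.08 on the log2 scale, and Spp1 rose by 0.53. Of 21 phagocytic receptors and opsonins, 8 rose and 7 fell (9 and 7 when adjusted over the list alone; camera adjusted p = 0.602), with the inhibitory Fc receptor Fcgr2b (1.80) and Cd14 (0.47) higher and the activating Fc receptor Fcgr1 (-1.29) and Axl (-0.77) lower. Of 30 lysosomal genes, 7 rose and 13 fell (7 and 14 when adjusted over the list alone; camera adjusted p = 0.259), with Psap (-0.53), Ctss (-0.36) and Lamp1 (-0.28) lower and Atp6v1h (0.53) higher. Of 16 antigen presentation genes, 6 rose, including the costimulatory Cd80 (1.12) and Cd83 (0.62), and 7 fell, including the immunoproteasome genes Psmb8 (-0.59) and Psmb9 (-0.79), which overlaps Tap1 on the other strand (camera adjusted p = 0.775). Of 10 complement genes, C3 (0.66) and C3ar1 (0.19) rose and Cfb (-0.58) and Itgax (-0.34) fell (camera adjusted p = 0.82).

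Among secreted and structural genes, matrix remodelling and migration had 8 of 15 members higher and 2 lower, with a median log2 fold change of 0.50 (camera adjusted p = 0.0011; adjusted p = 0.153 with an estimated correlation). Mmp13 and the urokinase receptor Plaur (1.24) rose, and the urokinase gene Plau (-0.91) and Cd44 (-0.36) fell. Of 13 trophic factors, Lif, Gdnf (from 7.60 ± 2.98 to 90.2 ± 21.6 normalized counts), Osm (2.39), Vegfa and Pdgfb (1.02) rose and Grn (-1.04) and Vegfb (-0.77) fell (6 and 3 when adjusted over the list alone), with a median of 0.41 (camera adjusted p = 0.0366; adjusted p = 0.181 with an estimated correlation). With a filter of 1 normalized count, the minimum planned before the data were examined for FPKM-like values, the median was 0.0766 (camera adjusted p = 0.0806). With quantile normalization Mdk (-1.01) and Igf1 (-0.61) fell too, and the list had a camera adjusted p = 0.0795. That list also lost its call without control replicate 3 (camera adjusted p = 0.0659) or without ferroptotic replicate 2 (0.0542).

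Of 27 glycolysis and hypoxia genes, 12 rose and 1, Ldha (-0.14), fell, with a median of 0.14 (camera adjusted p = 0.000576; adjusted p = 0.181 with an estimated correlation). The glucose transporter Slc2a1 (0.99), Ero1l (0.90), Ndrg1 (0.85) and Vegfa led it. Of 26 nuclear genes of oxidative phosphorylation, 0 rose and 13 fell (1 and 14 when adjusted over the list alone), by a median of -0.13 (camera adjusted p = 0.017; adjusted p = 0.257 with an estimated correlation), including Cox7a2 (-0.55), Sdha (-0.34), Atp5a1 (-0.25) and Atp5o (-0.22). With quantile normalization 8 of its members fell, Ndufa1 (0.25) and Uqcrc2 (0.14) rose, and the list had a camera adjusted p = 0.0795. Of 21 ER chaperones and unfolded protein response genes, 6 rose, including Herpud1 (1.17), Dnajb9 (0.67) and Sel1l (0.43), and 9 fell, including Edem1 (-0.62; camera adjusted p = 0.82). Of 14 heat shock genes, Dnajb4 (0.84), Hspa4l (0.54) and Hsp90aa1 (0.13) rose and 8 fell, including Hspa8 (-0.51) and Hspd1 (-0.42; camera adjusted p = 0.203).

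No tested list of markers of another cell type passed camera, though all 4 passed fry (adjusted p from 0.00284 to 0.00558). The list of ribosomal protein genes, fixed beforehand as a possible sign of RNA quality, did pass camera. That was in the same libraries in which stress genes rose and cell cycle genes fell. RNA quality itself was not measured here. Among astrocyte markers Gja1 (0.49) and Aldoc (0.26) rose and Aldh1l1 (-0.64) fell, 2 and 1 of 5 (camera adjusted p = 0.622). The call of Aldh1l1 was lost in 4 of 14 alternatives. Among oligodendrocyte markers Mag (1.01) rose and Cldn11 (-1.24), Mbp (-0.69) and Cnp (-0.14) fell, 1 and 3 of 6 (camera adjusted p = 0.481). Cnp overlaps Dnajc7 on the other strand and lost its call in 11 of 14 alternatives. Among fibroblast, pericyte and endothelial markers Dcn (from 8.49 ± 2.84 to 40.4 ± 18.1 normalized counts), Acta2 (0.99) and Pecam1 (0.51) rose, 3 of 6 (camera adjusted p = 0.192). Among markers of bone marrow-derived and border macrophages Lyz2 (0.14) rose and Itga4 (-1.73) and Emilin2 (-0.24) fell, 1 and 2 of 9 (camera adjusted p = 0.82). With quantile normalization, which sets each value by its rank in the library, the change of Lyz2 was -0.16. Tubb3 rose from 4.99 ± 2.54 to 61.3 ± 5.64 normalized counts, 1 of 3 neuronal markers measured, and S100a8 from 13.2 ± 3.46 to 144 ± 14.1, 1 of 2 markers of neutrophils and lymphocytes. Of 30 ribosomal protein genes, many of which have processed copies, 16 rose and 0 fell (18 and 0 when adjusted over the list alone), with a median of 0.10 (camera adjusted p = 7.97e-05; adjusted p = 0.268 with an estimated correlation), including Rpl7 (0.29). With quantile normalization 9 of them rose and with total-count scaling 12. Of 15 mitochondrially encoded transcripts, mt-Co3 (0.13) rose and mt-Nd1 (-0.58), mt-Rnr2 (-0.57) and mt-Nd2 (-0.36) fell (camera adjusted p = 0.616). Of these, mt-Co3, which overlaps mt-Atp6 on the same strand, lost its call in 7 of 14 alternatives and mt-Nd2 in 5. With quantile normalization 0 rose and 5 fell, mt-Cytb (-0.45) and mt-Co2 (-0.08) beside the 3 named.

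For 23 of the 33 lists tested, the counts adjusted over the list alone were those given. By camera with a preset correlation 12 lists were higher and 4 lower, and with an estimated correlation 3 held, namely interferon-stimulated genes, cytokines and cholesterol biosynthesis. By fry, which makes no comparison with other genes, 28 lists passed. The median and the direction of the camera test differed in sign for the astrocyte, oligodendrocyte and bone marrow-derived macrophage markers, none of which passed.

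The authors' deposited table lists 1699 changed genes, 930 higher and 769 lower, which are those with p under 0.05 and a log2 fold change of at least 1 in either direction. Of these, 319 have a false discovery rate of 0.05 or more in the authors' deposited table, up to 0.154, and 7113 genes of the whole table have one under 0.05. Among the genes tested here, 6964 have a false discovery rate under 0.05 in the authors' deposited table, and 6553 of them were also called by limma, all 6553 with the same sign. Of the authors' 1699 genes, 336 were left out by the low-count filter, and limma called 1191 of the remaining 1363.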

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

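The alternatives chosen after the data were seen were limma-voom on whole reads, total-count scaling and leaving out genes of wide spread. The minimum of 10 normalized counts was itself chosen after the data were seen, in place of a planned minimum of 1, under which 6658 of 20707 genes passed. Across the alternatives at an adjusted p of 0.05 the number of changed genes was 5798 to 6699, against 6629, and 4773 at an adjusted p of 0.01. Leaving out each library in turn gave 5798 to 6188, and 5598 to 5847 of the 6629 calls were kept. Quantile normalization turned the sign of 6 of the 6629 genes. Replicate numbers did not pair the samples (correlations of deviations 0.00859, -0.0196 and -0.0393), and with a replicate block 6226 genes passed, 6015 of them among the 6629; 3 named genes lost their call, Rbm12, Cnp and mt-Nd2.

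Of the 146 tested genes named by size of change, by smallest p-value in a list or from the fixed set, 137 kept their direction and side of the threshold under all 14 alternatives run for them; members named only because few were counted were not covered. Quantile normalization sets each value by its rank in the library. With it Lyz2 reversed to -0.16 (Lyz2 also lost its call without trend and robust). Spp1, the most abundant gene in every library, was fixed at 0 by construction. The other exceptions were Aldh1l1, Cnp, Rbm12, Rplp0, mt-Co3 and mt-Nd2, which each lost a call, and Gpx4, which passed with quantile normalization (0.12, limma adjusted p = 0.0224). The cause was not tested.

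Of the 16 lists that passed, 14 kept their call in every refit. Trophic factors lost it with no filter (median 0.0766), a filter of 1 normalized count (0.0766), quantile normalization (0.40) and limma without trend and robust (0.41), and without control replicate 3 or ferroptotic replicate 2, with medians without 1 library of 0.26 to 0.49. Oxidative phosphorylation lost it with quantile normalization (-0.0897). With an estimated correlation 3 lists passed and with fry 28. The medians of those that lost their call with an estimated correlation stay as they were, since that setting changes the test alone: 0.64 for NF-kB targets, 0.65 for alternative activation, 0.64 for NRF2, 0.36 for ferroptosis regulators, 1.55 for the integrated stress response, 0.14 for glycolysis and hypoxia, -0.13 for oxidative phosphorylation, -1.50 for cell cycle, 0.24 for p53 targets, 0.41 for trophic factors, 0.50 for matrix remodelling, 0.66 for immediate early genes and 0.10 for ribosomal proteins. The authors' deposited table holds 1699 genes by their threshold and 7113 by a false discovery rate under 0.05 alone. The edgeR and DESeq2 alternatives, planned for deposited counts, were left out and not run on the whole reads worked out here. Genes below 10 normalized counts were left out of the main test.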

Other observations

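The splits of the libraries were planned before the data were examined, but what their outcomes would mean was written after the results were seen. The gene families, the tests of a poor library, of carried-over RNA, of a residual inducer, of scaling and of the synthetases were chosen after the results were seen; the tests of overlapping gene models and of depth were set before their values were seen, though the limits that pick genes of wide spread were chosen after looking at the spans. Of 10 families picked after the data were seen, 8 passed camera with a preset correlation and 1 with an estimated correlation, and none turned the sign of its median with quantile normalization or total-count scaling. Of 10 guanylate-binding proteins, interferon-induced GTPases, 9 fell and 0 rose, with a median log2 fold change of -1.59 (camera adjusted p = 4.92e-05; adjusted p = 0.0946 with an estimated correlation), among them Gbp6 (-2.59), Gbp2b (-2.35) and Gbp2 (-1.98), close copies that can share reads. Of 19 replication factor, GINS and DNA polymerase subunits, 17 fell and 1, Pold4 (0.58), rose, with a median of -0.92 (camera adjusted p = 5.15e-09; adjusted p = 0.0251 with an estimated correlation). Of 30 genes with a Kif symbol, which are kinesins apart from the kinesin-binding protein Kif1bp, 14 fell, led by the mitotic Kif14 (-2.03) and Kif20a (-1.88), and 6 rose (14 and 9 when adjusted over the list alone), led by Kif21b (1.15; camera adjusted p = 0.019; adjusted p = 0.0946 with an estimated correlation). Of 8 genes of the interleukin-6 family and its feedback, 7 rose and 0 fell, with Il11 at 3.17, Socs3 at 2.37 and Clcf1 at 2.18 (camera adjusted p = 3.59e-06; adjusted p = 0.0573 with an estimated correlation). Csf2, picked out after its value was seen, went from 4.90 ± 4.49 to 429.5 ± 47.8 normalized counts (log2 fold change 6.72, SE 0.89; limma adjusted p = 0.002). Of 9 Toll-like receptors, Tlr2 (0.30) rose and Tlr7 (-2.06), Tlr3 (-1.57), Tlr8 (-0.92), Tlr9 (-0.64) and Tlr13 (-0.44) fell (camera adjusted p = 0.179). Tlr7 had 6792, 6412 and 2163 normalized counts in the control libraries (limma adjusted p = 0.0419), and Tlr8 went from 35.3 ± 4.40 to 18.6 ± 5.55 (limma adjusted p = 0.0484). Tlr4 (1.88, SE 0.94) did not pass (limma adjusted p = 0.193), with 444, 3025 and 3164 normalized counts in the libraries given ferroptotic medium. Of 9 interferon regulatory factors, Irf8 (0.18) rose and Irf4 (-0.72), Irf2 (-0.67) and Irf7 (-0.54) fell (camera adjusted p = 0.179).

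Of 24 amino acid transporters, 13 rose and 5 fell, with Slc1a4 at 2.23 and Slc6a9 at 1.83 (camera adjusted p = 0.000762; adjusted p = 0.0946 with an estimated correlation); the members that fell were Slc36a3 (from 19.7 ± 12.1 to 3.12 ± 2.74 normalized counts), Slc43a2 (-0.71), Slc43a3 (-0.62), Slc36a1 (-0.23) and Slc38a10 (-0.20). Of 31 genes whose symbols begin with Eif2 or Eif4, initiation factors with their kinases and binding proteins apart from the pseudogene Eif4a-ps4, 16 fell and 1 rose, the translation repressor Eif4ebp1 (1.35; camera adjusted p = 0.0111; adjusted p = 0.0946 with an estimated correlation). Eif4a-ps4 (-0.31) is among those that fell. Of 20 cytosolic aminoacyl-tRNA synthetases, 15 rose and 3 fell, Vars (-0.44), Qars (-0.13) and Kars (-0.11), with a median of 0.51 (camera adjusted p = 3.59e-06; adjusted p = 0.0946 with an estimated correlation). Of 17 mitochondrial synthetases, 8 fell and 1, Fars2 (0.28), rose, with a median of -0.16 (camera adjusted p = 0.0234; adjusted p = 0.0946 with an estimated correlation). The medians of the 2 sets differed by 0.66. As the sets and the comparison were picked after these values were seen, a permutation of the family of each gene (two-sided p = 0.00224 over 100000 resamples, with genes not independent) restates the difference and settles nothing about its cause.

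As to whether chance can be excluded, the real split gave 6629 genes and the highest of the other splits gave 3, with 1193 and 3 for genes changed at least 2-fold; 1 of 10 splits gave as many in each case, and with 10 splits a share under 0.05 cannot be reached.

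For the rise of stress and cytokine genes, RNA carried over from the dying macrophages was tested with 12 macrophage transcripts whose mean over the control libraries was under 100 normalized counts, of 23 considered. Their sum was 171 ± 39.0 and 172 ± 25.4 normalized counts, a rise of 0.000643% of that of Hmox1. These transcripts thus did not rise as a set beyond their spread, but Apoe weighs heavily in the sum and in its spread. Apoe had 141, 62.2 and 78.3 normalized counts in the control libraries and 67.0, 74.7 and 79.7 in the others. A rise of the other transcripts could thus be masked, and their sum was not tested alone. No macrophage sample is among the groups. The level of these transcripts in the dying macrophages is therefore not known, and the test does not measure carry-over. Lyz2 was left out because the control libraries already held 207348 normalized counts, and it rose to 229156. Its log2 fold change with quantile normalization was -0.16, but that setting fixes each value by its rank in the library. That value therefore does not undo the rise of Lyz2. S100a8 rose too, from 13.2 to 144, so carry-over is not excluded. Residual inducer in the medium may also raise such genes. The rise of 23 of 23 genes of the integrated stress response is part of the pattern to be explained and is no evidence for it. A residual inducer, which is not named in the sources used here, cannot be told apart from factors released by ferroptotic cells, since no group received the inducer in fresh medium. The response to the medium, the biological difference of the design, stays open beside it.

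Cell cycle and interferon-stimulated genes fell together, 60 of 62. Under total-count scaling and quantile normalization 60 still fell at the fewest. Total-count scaling moved the medians of the interferon-stimulated and cell cycle lists further down, to -0.907 and -1.52, so it could hardly take calls away. With quantile normalization they were -0.864 and -1.45, against -0.887 and -1.50, which argues against the choice between these scalings as the source. With every library thinned to 39624311 reads, 60 fell again and 6626 genes passed in all, against 6629. Thinning changed so little that this outcome was close to fixed beforehand and does not decide on depth. The medium itself stays open as the biological explanation, as a hypothesis that these data do not separate from a residual inducer.

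In 68 genes with at least 500 normalized counts, the libraries of 1 group spanned more than 1.5 log2 units, and 1 of them, Tlr7, was called. Exons of 52.9% of these genes overlapped those of another gene, against a median of 33.8% and a 95th percentile of 42.6% in 10000 lists matched on expression. Reads assigned to one or the other of overlapping models may thus account for part of the spread. For 11 of the 36 overlapping genes the sum with a partner spanned under 0.5 log2 units, as for Taf9 with Ak6 (2.13 to 0.0590). A sum with a far more abundant and steady partner spans little in any case. In Adat3 and Scamp4 both partners spread, in opposite directions. Normalized control counts were 213.5, 2064 and 1994 for Adat3 and 2049, 412 and 456 for Scamp4. Their sum spanned 0.130 log2 units. Gm21982 and Rbm42 did likewise with ferroptotic medium (2125, 2121 and 107 against 1213, 970 and 2991). A steady partner cannot account for these pairs, each of which enters the 11 with both members. For the other genes the spans of the partners were not compared, so the count as a whole cannot show that reads were shared. The library most often outlying was so in 23.5% of the genes. That share is over both groups, while the outlying library was sought only in the wider group. Control replicates 1, 2 and 3 were outlying in 16, 10 and 7 genes, and ferroptotic replicates 1, 2 and 3 in 12, 8 and 15. No single library thus held most of these genes, but a poor library behind part of the spread is not excluded. The spread of the other genes stays open, and no biological explanation was tested.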
